A study of Mus musculus with 8 samples.

How the data were processed

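RNA was measured in 8 libraries of mouse brain neural progenitor cells, the self-renewing precursors of neurons and glia, which carried lentiviral hairpins against FUBP1, against CIC or against no mouse gene (non-targeted, NT). FUBP1 (far upstream element-binding protein 1) is a single-stranded nucleic acid-binding regulator of transcription and splicing, and CIC (capicua) is a transcriptional repressor. Per the labels' protocols, the cells were selected with puromycin for 3 days and were either kept proliferating in N2 medium with 20 ng/ml each of EGF and bFGF or moved to neurobasal medium with B27 for 5 days, and total RNA went into TruSeq libraries. There were 2 NT libraries in each state and 1 library for each targeted gene in each state. The NT libraries carried the names TRC (replicate 1) and GFP (replicate 2) in the proliferating state and 7 (replicate 1) and GFP-D (replicate 2) in the differentiating state. The 4 others were named FUBP1, FUBP1-D, CIC and CIC-D. Nothing in the labels says that the NT replicates were separate cultures, and their names point to different constructs. The p-values thus measure the spread between these libraries, which may be technical in part. In the additive model described below they measure also how far knockdown effects differ between states. Technical spread alone would not give the differences that recur in both states, such as those of Cdkn2a and Pcdhgb6 (chosen after their values were seen), which are low in both GFP and GFP-D. Replicate numbers follow the order of deposition and pair no libraries.

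The values are FPKM, fragment counts scaled by transcript length and by the size of the library, 1 per gene and library, in a single table deposited by the authors. Per the submitters' processing notes, the tools included bcl2fastq 2.17, cutadapt, TopHat2 2.0.11 and Cufflinks 2.1.1, and the genome build was mm9. Their order, settings and gene annotation, and whether strand was used, are not given in the sources used here, so genes that overlap on opposite strands or share sequence with close relatives, the clustered protocadherins among them, are uncertain. The table held 20793 rows with 20462 distinct gene symbols, and 519 rows shared a symbol with another row. In 4069 rows every library was at 0. In 3 rows 1 library was listed at 0 while all others lay above 5 FPKM (Gtf2i in TRC, Actr3 in GFP-D and Nfe2l1 in CIC-D). Such a 0 can be a failed estimate, so a gene at 0 is described only as listed at 0. Positions are mm9 coordinates from the table, counted from 1. The table holds 1 value per gene, so splice isoforms, Kdm1a exon use included, were not analysed here.

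The table gives no fragment counts. Low FPKM values moved in steps, and the size of a step depends on the gene's length and on the number of fragments the authors normalized to. Relative to TRC, the most frequent step ratio among rows up to 0.2 FPKM was 0.966 in GFP, 1.05 in FUBP1, 0.948 in CIC, 1.34 in 7, 1.27 in GFP-D, 1.31 in FUBP1-D and 1.20 in CIC-D. Between 23.5% and 42.9% of the 396 to 796 rows compared lay within 5% of that ratio. A larger step makes low values coarser, so they are coarser in the differentiating libraries than in TRC. It would mean fewer fragments there if the values were scaled by the fragment total alone. The sources used here do not say whether they were. The absolute depth is unknown. The FPKM values of a library summed to between 426984 (FUBP1-D) and 541608 (GFP).

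FPKM values were used as deposited, without rescaling, as log2(FPKM + 1). Rows with at least 1 FPKM in 2 or more libraries were kept, which left 11968 rows and 11967 symbols. Changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Tests used limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend, two-sided), with Benjamini-Hochberg adjustment over the 11968 rows and a threshold of 0.05. Differentiation across arms, FUBP1 knockdown, CIC knockdown and FUBP1 against CIC came from an additive model of state and targeted gene over the 8 libraries, with 4 residual degrees of freedom. Its residual holds the spread between the NT libraries and any difference of a knockdown effect between states. The fit takes libraries that share a name across states, such as CIC and CIC-D, as independent of each other. Differentiation within the NT libraries, and the differences of the knockdown effects between states, came from 6 group means with 2 residual degrees of freedom, both from the NT pairs, so the single knockdown libraries were assumed to vary like NT libraries. A single knockdown library was also set against each of the 2 NT libraries of its state, as a description without a test. The percentile of a list's median there was taken among 10000 random lists matched on mean expression.

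The design, the tests, the rule for naming genes and 23 gene lists (505 distinct gene symbols) were fixed before the data were examined. The lists covered cell cycle, neural progenitors, neurons, astrocytes, oligodendrocytes, microglia, endothelium, mesenchyme, ependyma and choroid plexus, CIC targets, the FUBP family with its partners and reported targets, LSD1 (the histone demethylase encoded by Kdm1a) complexes, splicing regulators, Notch, Sonic hedgehog and Wnt, interferon response, p53 targets, integrated stress and unfolded protein responses, cholesterol synthesis, glycolysis and hypoxia, immediate early genes, synapses and channels, and extracellular matrix and adhesion. A gene can stand in more than 1 list. Lists with 5 or more kept members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. The mixed form of fry, which counts changes in either direction, was not used to call lists. It passed in 18 of 19 lists for differentiation across arms, 12 for differentiation in NT, 0 for FUBP1 knockdown, 1 for CIC knockdown, 2 for FUBP1 against CIC and 0 for either difference between states. Fubp1, Cic and Kdm1a are always named. Beyond these, the text names up to 10 genes per direction with the largest change among those past the threshold, with a mean of at least 5 FPKM in a compared group and with no overlap between the compared libraries within each state, and up to 4 members of smallest p per list. For a single library, it names up to 5 genes per direction by the smaller of the 2 differences from the NT libraries. Genes without a proper name were counted but not named, and some genes that the rule names are not reported here. Genes outside this rule are said to be chosen after their values were seen.

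The fits were tested on simulated data built from the real means and residual spreads of 11968 genes, with 200 genes changed. The changed genes were drawn from those with a mean level of at least about 5 FPKM. The numbers recovered thus say nothing about lower genes. All simulated libraries were independent, including those that share a name across states. For differentiation across arms, 26 of 67 genes changed by 1 log2 unit, 58 of 67 changed by 2 and 65 of 66 changed by 4 were recovered, with 12 false calls. For FUBP1 knockdown, 8 of 67, 47 of 67 and 61 of 66 were recovered at 1, 2 and 4 log2 units, with 5 false calls, and for CIC knockdown 12 of 67, 47 of 67 and 62 of 66, with 6 false calls. For FUBP1 against CIC, 3 of 67, 47 of 67 and 62 of 66 were recovered, with 5 false calls. For differentiation within NT, 0 of 67, 5 of 67 and 48 of 66 were recovered, with 0 false calls. For the difference of the FUBP1 effect between states, and likewise for CIC, 0 of 66 genes changed by 4 log2 units were recovered, so a count of 0 in those comparisons carries little information about single genes.

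The alternatives were other pseudocounts (0.1 and 5), no filter on low values, a filter of at least 5 FPKM in 2 libraries, quantile normalization, rescaling by the median of ratios, no mean-variance trend, group means in place of the additive model, a block on the name shared across states, the 4 NT libraries alone, and leaving out each library in turn. Chosen after seeing the data were fits without GFP and GFP-D, without 7 and FUBP1-D, without CIC and CIC-D, with TRC, 7 and the 2 FUBP1 libraries alone, and with GFP and GFP-D as the controls for CIC. For crossed labels in the FUBP1 arm, the rule first used the share of genes with the same direction alone, and the correlations of FUBP1 and TRC with 7 and FUBP1-D were added after the results were seen, which left this explanation open. The explanation by partial differentiation of the GFP culture was likewise narrowed to a mixture of cells. For carried-over cells or reads in FUBP1-D, the first test used 40 genes outside the cell cycle list, and as most of them serve division it was replaced by one on the 7 that do not, picked from these 40 after their values were seen. Python 3.11.15 and matplotlib 3.10.9 drew the figures.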

Results

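Gene expression was measured by RNA sequencing in 8 libraries of mouse neural progenitor cells that were kept proliferating or had been moved to differentiation medium for 5 days. The cells carried hairpins against FUBP1, against CIC, or non-targeted (NT) hairpins, with 2 NT libraries and 1 library for each targeted gene per state. The series concerns FUBP1, the splicing of LSD1 and the terminal differentiation of neural progenitors. The comparisons below address the transcripts that change on differentiation and with each hairpin at the level of whole genes. The number of fragments per library is unknown. Between 10702 genes (CIC) and 11529 genes (FUBP1-D) reached 1 FPKM in a library.

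The targeted genes were examined first, in every library. Fubp1 (chromosome 3, 151873422 to 151899794, mm9) stood at 50.2 FPKM in the proliferating NT library labelled TRC and at 12.4 FPKM in the other one, labelled GFP. The proliferating library labelled FUBP1 held 34.8 FPKM, which was 69.3% of TRC but 280% of GFP, and the proliferating library labelled CIC also held 34.8 FPKM. In the differentiating state, Fubp1 was at 24.8 FPKM in the NT library labelled 7, 25.4 in GFP-D, 21.6 in FUBP1-D and 26.9 in CIC-D. Across states, Fubp1 differed between the libraries labelled FUBP1 and the NT libraries by 0.12 on the log2 scale (SE 0.48, limma adjusted p = 0.999). The lowest Fubp1 level thus belonged to a library labelled non-targeted, and every direction given for the FUBP1 arm below is that of the labels. Without GFP the difference was -0.32, and without the proliferating library labelled FUBP1 it was -0.15. Cic (chromosome 7, 26067198 to 26079167) was at 13.3 FPKM in the proliferating library labelled CIC, which was 33.6% of TRC and 39.2% of GFP, and at 25.6 FPKM in CIC-D, which was 60.9% of 7 and 72.5% of GFP-D. Both libraries labelled CIC lay below both NT libraries of their state, but the fitted change of -0.98 (SE 0.30) did not pass the test over all genes (adjusted p = 0.332). Kdm1a (chromosome 4, 136106448 to 136158638), which encodes LSD1, ranged from 35.6 to 50.6 FPKM. Its difference was 0.0019 (SE 0.20, adjusted p = 0.999) with the FUBP1 label and -0.16 (SE 0.20, adjusted p = 0.783) with the CIC label, and with the FUBP1 label its sign changed under both rescalings.

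**Figure D1:**
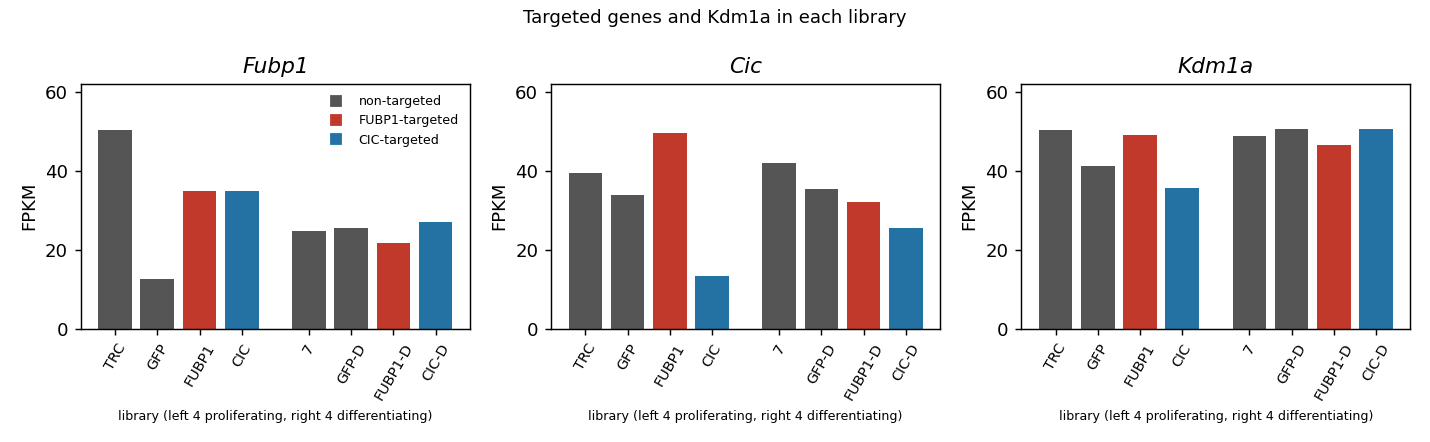
FPKM (vertical axis, from 0) of Fubp1, Cic and Kdm1a in each of the 8 libraries (horizontal axis), with 1 bar per library and no error bars, coloured by the targeted gene of the label. Fubp1 is lowest in the NT library labelled GFP at 12.4 FPKM, Cic is lowest in the library labelled CIC at 13.3 FPKM, and Kdm1a lies between 35.6 and 50.6 FPKM.

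The differentiating libraries held less of the transcripts of dividing cells and more of those of astrocytes than the proliferating ones. All 40 genes of the cell cycle list fell, among them the replication licensing factors Mcm5 (from 47.9 ± 20.8 to 0.578 ± 0.709 FPKM, SD, n = 4 and 4), Mcm2 (from 58.4 ± 14.5 to 4.14 ± 0.457), Mcm3 and Cdt1. Among the largest decreases were also Ube2c, a ubiquitin-conjugating enzyme of mitotic exit (from 160 ± 71.2 to 3.15 ± 5.16 FPKM), the mitotic kinases Pbk and Aurkb, the anaphase activator Cdc20, Ccnb1 (cyclin B1), Cdca8, Fam64a, Tmem173 (STING, an adaptor in the response to cytosolic DNA) and Nptx1, a secreted neuronal pentraxin (from 155 ± 93.7 to 1.90 ± 1.32 FPKM). The genes with the largest increases were C3, the central complement component (from 1.56 ± 1.47 to 368 ± 306 FPKM), Pla2g7, Ndrg2 (from 10.1 ± 7.94 to 323 ± 148), the water channel Aqp4 (from 4.64 ± 5.85 to 129 ± 87.3), Nrbp2 (from 6.87 ± 3.06 to 223 ± 105), C1s, Dhrs3, Phyhd1, Ogn and the angiotensin precursor Agt. The log2 changes of these genes ran from 4.23 (Agt, SE 0.48, adjusted p = 0.0012) to 6.80 (C3, SE 0.79, adjusted p = 0.0014). Among the 10 largest decreases under the naming rule, which leave out Mcm2, Mcm3 and Cdt1, they ran from -4.50 (Aurkb, SE 0.35, adjusted p = 5.8e-04) to -5.79 (Ube2c, SE 0.53, adjusted p = 7.9e-04).

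Astrocyte markers rose in 11 of the 19 kept members and none fell, with Clu from 3.16 ± 3.31 to 50.4 ± 20.5 FPKM (SD, n = 4 and 4) beside Ndrg2, Aqp4 and Agt. Adjusted over the list alone, 12 rose. Neuron markers went both ways, 4 up and 3 down of 16 kept members: Scg3 rose from 2.32 ± 1.91 to 28.9 ± 22.1 FPKM, whereas Gap43, a growth cone protein, and Dlx1 fell. Only 16 of the 35 neuron genes passed the filter on low values, and the median of the 35 genes' highest FPKM was 1.83. Among oligodendrocyte-lineage genes 3 rose and 3 fell of 13, with Olig2 falling from 342 ± 47.9 to 128 ± 38.8 FPKM and the myelin gene Cnp rising from 62.2 ± 15.6 to 167 ± 76.1. Progenitor markers split likewise, 5 up and 4 down of 21: Sox9 rose from 31.4 ± 6.55 to 90.5 ± 15.3 FPKM, while Fabp7 (from 1554 ± 651 to 267 ± 238), Hmga2 (from 132 ± 60.2 to 20.2 ± 9.38) and the Notch effector Hes1 fell. The camera test called the cell cycle list lower (adjusted p = 1.2e-24) and the astrocyte list higher (adjusted p = 4.8e-04). Neither call held with an estimated correlation (adjusted p = 0.381 for both), while fry called both lists (adjusted p = 0.00481).

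In 3 further lists most of the called members fell, and in the interferon list the called members rose. Of the 18 genes of the CIC target list, many of which also respond to ERK signalling, 13 fell and 1 rose, and adjusted over the list alone 14 fell. They included the feedback regulators Dusp6 (from 146 ± 47.3 to 15.4 ± 6.80 FPKM, SD, n = 4 and 4), Spry1 (from 65.9 ± 28.9 to 5.81 ± 1.12) and Spry4 (from 42.6 ± 14.6 to 5.63 ± 1.59), and Ccnd1 (cyclin D1, from 968 ± 241 to 114 ± 50.7). Cholesterol synthesis genes fell in 11 of 20 members, with all 20 estimates negative, among them Fdps (from 181 ± 129 to 32.1 ± 13.2 FPKM). Their mean log2 level was 6.33 in TRC and 6.26 in FUBP1. It was lower in GFP (4.73) and CIC (4.80) than in the differentiating FUBP1-D (4.92), though above GFP-D (3.66) and CIC-D (3.88). Splicing regulators fell in 14 of 30 and rose in 1, including Srsf3 (from 208 ± 52.3 to 49.9 ± 19.4 FPKM), Tra2b (from 138 ± 40.4 to 44.3 ± 8.76), U2af1 and Khdrbs1. The mean log2 level of this list was about as high in FUBP1-D (5.29) as in GFP (5.27). Interferon response genes rose in 8 of 25 with none falling, and in 6 adjusted over the list alone, with Ifit3 from 4.46 ± 2.86 to 124 ± 134 FPKM and Gbp2 from 11.1 ± 7.56 to 119 ± 85.7. Their mean log2 level ranged from 3.46 in GFP-D to 5.56 in CIC-D within the differentiating state, and it was lower in GFP-D than in GFP but higher in 7 (5.42) than in TRC (2.67). The camera test called these 4 lists (adjusted p = 2.0e-05, 5.8e-05, 0.0020 and 0.0058, in this order), and none held with an estimated correlation (adjusted p = 0.381, 0.843, 0.843 and 0.866). Of the 4, fry called the CIC target list alone (adjusted p = 0.00481).

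Camera did not call the other lists, and of these fry, which tests a list by itself, called the synapse and channel (adjusted p = 0.00498) and the Sonic hedgehog and Wnt list (0.0265). Among LSD1 complex genes, 3 rose and 3 fell of 16, with Hdac1 (from 92.5 ± 16.2 to 35.3 ± 13.7 FPKM, SD, n = 4 and 4) and Hdac2 lower, and Phf21a and Svil higher. In the FUBP family list, Myc fell from 46.9 ± 20.1 to 17.5 ± 6.60 FPKM together with Ccnd2, and Bcl2 rose, of 11 members. Notch genes rose in 4 and fell in 3 of 14, where Notch2 rose from 9.48 ± 1.89 to 64.2 ± 23.5 FPKM and Jag1 fell. Synapse and channel genes rose in 8 and fell in 3 of 21, with the glutamate receptor Gria1 rising from 2.23 ± 1.41 to 45.3 ± 36.9 FPKM. Matrix genes rose in 6 and fell in 3 of 23, with Spp1 (osteopontin) falling from 320 ± 245 to 21.1 ± 19.7 FPKM. Sonic hedgehog and Wnt genes rose in 3 of 13 (Ptch1, Wnt5a and Wnt7a). p53 targets rose in 2 and fell in 2 of 19, with the death receptor Fas rising from 4.01 ± 1.76 to 91.1 ± 32.2 FPKM. Glycolysis and hypoxia genes rose in 2 and fell in 3 of 20 (Pkm, Ldha and Pgk1 lower, Ndrg1 higher). Immediate early genes rose in 2 and fell in 4 of 15, and stress response genes fell in 4 of 20 (Atf4, Psat1, Asns and Sdf2l1). The microglia, endothelium, mesenchyme and ependyma lists kept only 2, 1, 3 and 4 members and were not tested. Their highest members were Cd68 at 7.14, Flt1 at 4.46, Fbln2 at 66.9 and Foxj1 at 47.6 FPKM.

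Over all genes, limma called 4647 of 11968 genes, 2533 higher and 2114 lower in the differentiating libraries. The larger side changed with rescaling, to 2040 higher and 2215 lower with quantile normalization and 2267 higher and 2353 lower with the median of ratios. With group means in place of the additive model 2906 genes were called, and without the library labelled FUBP1 or FUBP1-D 2498 or 2482. Without both 7 and FUBP1-D 883 were called.

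**Figure D2:**
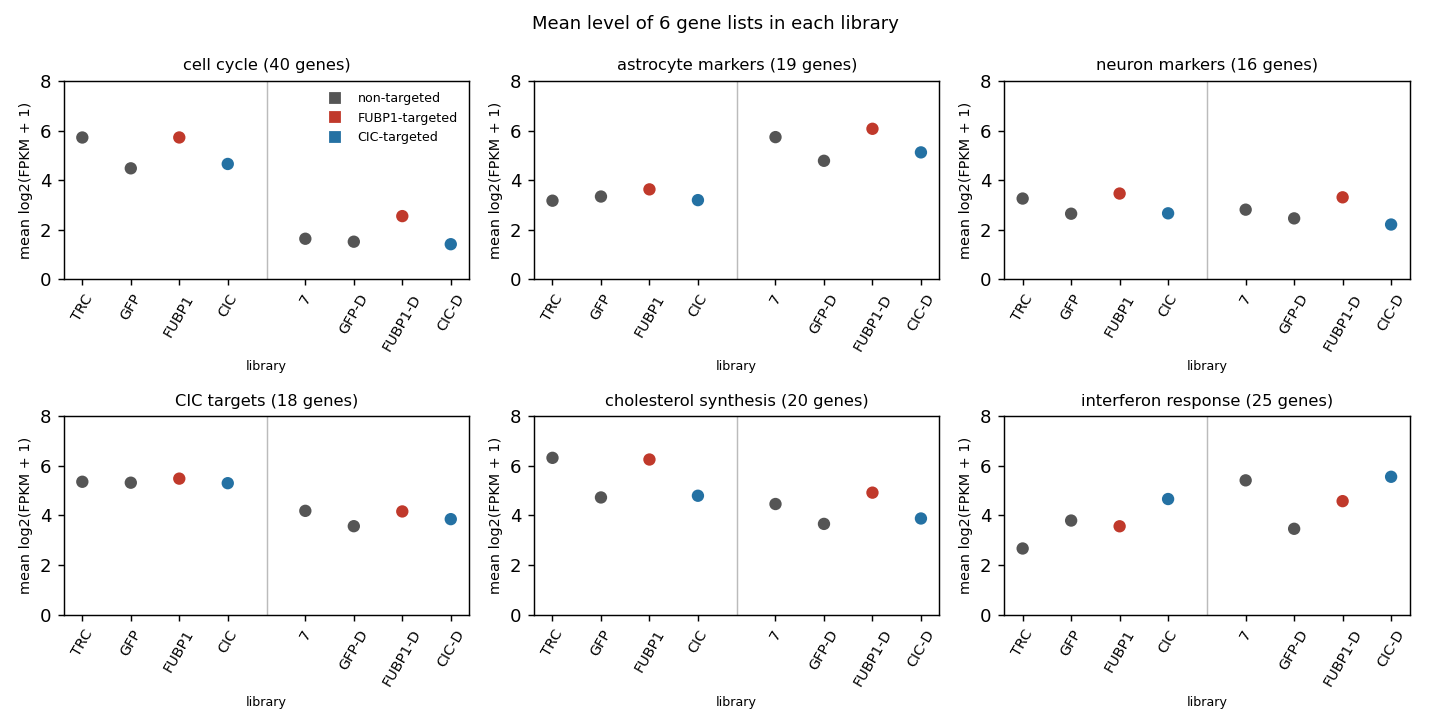
Mean log2(FPKM + 1) (vertical axis) of the kept genes of 6 lists in each library (horizontal axis), with proliferating libraries left and differentiating libraries right of the grey line, 1 point per library, coloured by the targeted gene of the label. The cell cycle list falls from between 4.47 and 5.72 in the proliferating libraries to between 1.41 and 2.55 in the differentiating ones, with FUBP1-D the highest of these.

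Between the NT libraries of the 2 states, in the group-mean fit to all 8 libraries, 20 of 40 cell cycle genes fell and 2 of 19 astrocyte genes rose. Called genes that rose included Nrbp2, the sphingosine phosphate receptor S1pr3, the chaperone Clu (from 1.02 ± 0.095 to 36.6 ± 10.3 FPKM, SD, n = 2 and 2), Agt, the transglutaminase Tgm2, Fas (from 4.68 ± 2.64 to 91.8 ± 32.4), the GABA transaminase Abat (from 2.18 ± 0.0040 to 50.8 ± 7.54), Amy1, Galnt16 and Nsg2. Called genes that fell were led by Nptx1 (from 195 ± 85.2 to 1.89 ± 1.79 FPKM), Ube2c, Mcm5, Fam64a, the cyclins Ccnb2 and Ccnb1, the thymidine kinase Tk1, Cdca3, Knstrn and Aurkb. Adjusted over the list alone, 40 cell cycle genes fell and 10 astrocyte genes rose. Camera called these lists (adjusted p = 7.5e-30 and 1.3e-04) and those of CIC targets (6.0e-06), cholesterol (3.1e-05), interferon (0.0047) and splicing (0.029), and none held with an estimated correlation (adjusted p from 0.952 to 0.996). In all, limma called 175 genes (69 higher and 106 lower, smallest adjusted p = 0.0435). The count was 0 without TRC, without 7 or without GFP-D and 480 without GFP. It was also 0 with a pseudocount of 5 or without the filter on low values. With the 4 NT libraries fitted alone it was 207 (82 higher and 125 lower).

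No gene was called between the libraries labelled FUBP1 and the NT libraries (0 of 11968 in limma, with 256 genes at an unadjusted p under 0.05, where 598 would be expected by chance). The proliferating library labelled FUBP1 correlated with TRC at 0.980 over the kept genes, the highest of all pairs, while TRC and GFP correlated at 0.914. In the simulation 8 of 67 genes changed by 1 log2 unit were recovered, so the count of 0 does not exclude changes of that size. The cell cycle genes of smallest p were Mki67 (15.7 ± 20.4 FPKM in NT, SD, n = 4, and 31.7 ± 36.4 with the FUBP1 label, n = 2, with both states in each SD) and Cdc20, with log2 differences of 1.73 (SE 0.43) and 2.09 (SE 0.68), both at a limma adjusted p of 0.999. Cholesterol synthesis genes had positive estimates in 20 of 20 members and cell cycle genes in 38 of 40, whereas glycolysis and hypoxia genes had a positive estimate in 1 of 20 (Vegfa 113 ± 50.5 against 33.3 ± 8.80 FPKM) and p53 targets in 2 of 19 (Cdkn1a 102 ± 39.4 against 49.6 ± 16.3). The LSD1 complex list was not called (median 0.14, camera adjusted p = 0.183), nor was the FUBP family list (median 0.12, camera adjusted p = 0.976). At the preset correlation camera called the cell cycle (median log2 difference 0.82, adjusted p = 3.0e-15), cholesterol (0.78, 4.4e-09), astrocyte (0.65, 3.8e-04), neuron (0.45, 0.0014), splicing (0.27, 3.8e-04), Notch (0.26, 0.0036) and CIC target (0.22, 0.036) lists higher. It called the glycolysis and hypoxia (-0.54, 4.4e-09), p53 (-0.54, 2.9e-06), immediate early (-0.45, 7.8e-05) and stress response (-0.34, 0.0039) lists lower. None of these held with an estimated correlation (adjusted p from 0.242 to 0.365). The 2 proliferating NT libraries differed from each other in these lists, with medians for TRC minus GFP of 1.34 over the cell cycle, 1.64 over the cholesterol and -0.98 over the p53 list. The count of genes stayed at 0 in every alternative run.

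Set against each NT library of its state, without a test, the proliferating library labelled FUBP1 lay more than 1 log2 unit above both in 84 genes and below both in 15. The GABA transporter gene Slc6a11 (19.6 FPKM against 0.600 in TRC and listed at 0 in GFP), Chn2, the imprinted gene Peg10 (105 against 13.4 and 5.63) and Pcdhga5 were among the furthest above, and Tmem35, Ccl17, Vegfc, Gfra1 and Man1a the furthest below. In the differentiating state FUBP1-D lay above both NT libraries by that margin in 89 genes and below both in 84. The retinaldehyde dehydrogenase Aldh1a1 (32.7 FPKM against 1.21 in 7 and 2.79 in GFP-D), S100a4 (311 against 35.3 and 29.0), Cdc20, Ube2c and Ccnb2 were the furthest above, and Itm2a (1.73 against 23.3 and 17.5), Cntf, Chchd10, Gpnmb and Gdpd3 the furthest below. Cell cycle genes lay above both NT libraries in 35 of 40 members in FUBP1-D, with a median difference of 1.05 on the log2 scale from the NT mean, and cholesterol genes in 19 of 20 (0.87). Glycolysis and hypoxia genes lay below both in 14 of 20 (-0.80). No random list of matched expression among 10000 reached these medians, which describes these libraries and not the condition. In the proliferating library labelled FUBP1, cell cycle genes lay above both NT libraries in 22 of 40 members (median 0.01 against TRC and 1.34 against GFP) and cholesterol genes in 6 of 20 (-0.14 and 1.49), and glycolysis and hypoxia genes lay below both in 10 of 20 (-0.29 and -0.30).

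The libraries labelled CIC held very little of several transcripts that were abundant in the NT libraries. Serpinh1, the collagen chaperone HSP47 (chromosome 7, 106493885 to 106501749, mm9), was at 0.190 ± 0.025 FPKM (SD, n = 2) against 108 ± 21.9 in NT (n = 4), a log2 change of -6.49 (SE 0.25, adjusted p = 1.6e-04). The lysosomal protease Ctsz (0.259 ± 0.189 against 108 ± 57.2 FPKM, log2 change -6.28, SE 0.62, adjusted p = 0.021), the membrane metalloproteinase Mmp14 (0.049 ± 0.051 against 48.5 ± 22.8, log2 change -5.46, SE 0.48, adjusted p = 0.016) and the galectin Lgals3 (1.38 ± 0.246 against 121 ± 105, log2 change -5.32, SE 0.62, adjusted p = 0.038) followed. Hdgfrp3, Mfsd10, Eml2, Zfp707, Epb4.1 and Efs were called with log2 changes between -2.39 (Efs) and -3.44 (Hdgfrp3). Fam5c (21.3 ± 7.89 against 0.461 ± 0.645 FPKM) and the clustered protocadherin Pcdhga10 (16.2 ± 4.87 against 0.454 ± 0.818) were called higher. Each SD in this paragraph spans both states. The matrix and adhesion list was not called (13 of 23 estimates positive, median 0.18, camera adjusted p = 0.443).

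The list of CIC targets did not move as a group with the CIC label. Of its 18 genes 10 had positive estimates and 0 were called, with a median log2 change of 0.07 and a camera adjusted p of 0.855. The members of smallest p were Spry4 (34.8 ± 39.0 FPKM with the CIC label, SD, n = 2, against 18.0 ± 15.7, n = 4), Dusp5 (1.84 ± 0.683 against 5.37 ± 2.25), Spry1 (18.9 ± 19.8 against 44.3 ± 46.7) and Dusp6 (51.6 ± 60.1 against 88.1 ± 91.5). Each SD in this paragraph spans both states, so it is not a spread between replicates. Interferon response genes had positive estimates in 23 of 25 members (median 1.33, camera adjusted p = 5.4e-10, and adjusted p = 0.724 with an estimated correlation), with Isg15 at 332 ± 16.0 against 64.7 ± 56.4 FPKM. Stress response genes had positive estimates in 17 of 20 (median 0.95, camera adjusted p = 2.2e-04, 0.724 with an estimated correlation), with Ddit3 at 387 ± 385 against 47.0 ± 29.5 FPKM, and p53 targets in 15 of 19 (median 0.41, camera adjusted p = 0.0035, 0.724 with an estimated correlation), with Cdkn1a at 331 ± 94.6 against 102 ± 39.4. The FUBP family list, which also holds Cdkn1a, was called higher (median 0.27, camera adjusted p = 0.032) and the cell cycle list lower (median -0.30, camera adjusted p = 0.041). No member of these lists was called over all genes, and no list call held with an estimated correlation (adjusted p = 0.724 for each of the 5). The NT libraries differed from each other over the interferon list, with medians of -1.07 for TRC minus GFP and 1.95 for 7 minus GFP-D. The cell cycle call was lost without TRC (median -0.015, adjusted p = 0.998), without the proliferating library labelled CIC (0.163), without 7 (0.0879), without CIC-D (0.0676) and without both 7 and FUBP1-D (0.117), and with GFP and GFP-D as the only controls the median turned to 0.11 (0.610). Astrocyte markers went both ways (11 of 19 estimates positive, camera adjusted p = 0.604) and 0 were called over all genes. Adjusted over the list alone, Clu (43.1 ± 49.6 against 18.8 ± 21.4 FPKM) and S100b (5.62 ± 5.00 against 0.306 ± 0.092) were higher, and Aldh1l1 (10.5 ± 10.2 against 88.2 ± 59.7) and Sparcl1 (14.5 ± 13.3 against 157 ± 138) lower. Of the 19 lists, only this one passed the mixed form of fry with the CIC label (adjusted p = 0.00833).

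In all, limma called 13 genes with the CIC label, 2 higher and 11 lower. The fit counted CIC and CIC-D as independent. Their deviations from the state means correlated at 0.267 across genes, but an effect of the hairpin in both states would give this too. This value therefore does not decide whether they were independent. If CIC and CIC-D came from the same culture, the p-values given for the CIC label are too small. The count was 4 without GFP, 6 without GFP-D, 2 without either library labelled CIC, 1 with group means and 2 without the filter on low values, and it was 230 (83 higher and 147 lower) with GFP and GFP-D as the only controls. With a pseudocount of 0.1 it was 35, all lower, and with a pseudocount of 5 it was 4, of which 2 were higher.

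**Figure D3:**
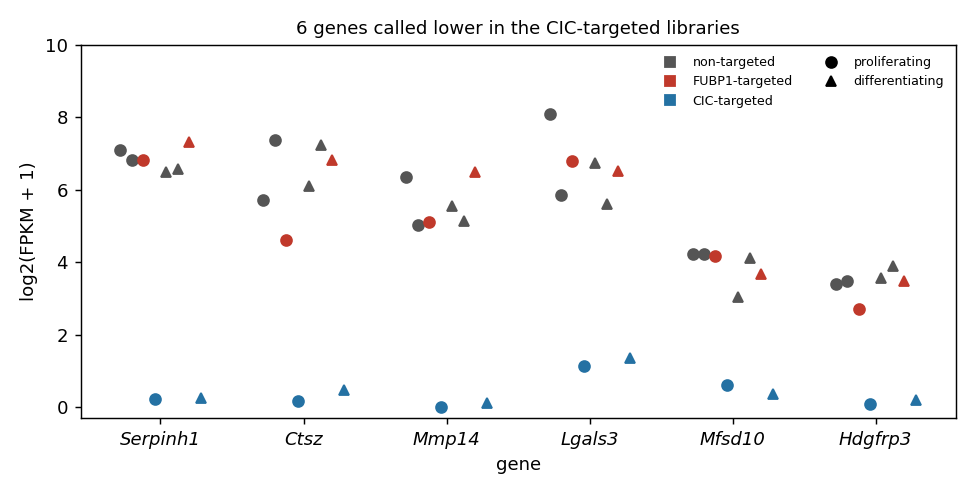
Values on the log2(FPKM + 1) scale (vertical axis) of 6 genes called lower in the libraries labelled CIC (horizontal axis), with 1 point per library, circles for proliferating and triangles for differentiating libraries, coloured by the targeted gene of the label. The libraries labelled CIC are the lowest for each gene, at 0.172 and 0.207 FPKM for Serpinh1, while the 6 other libraries lie between 88.2 and 157 FPKM for it.

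Set against each NT library without a test, the proliferating library labelled CIC lay more than 1 log2 unit above both in 364 genes and below both in 569. St3gal6 (109 FPKM against 2.22 in TRC and 0.427 in GFP), the stress-induced factor Atf3 (82.2 against 0.943 and 2.01), Gap43 (250 against 2.68 and 8.14), Fam5c and Gucy1b3 were the furthest above, and Spp1 (16.1 against 465 and 564) stood among the furthest below with Serpinh1, Ctsz, Mmp14 and Lgals3. CIC-D lay above both NT libraries by that margin in 103 genes, among them Hsd11b1 (43.9 FPKM against 2.47 in 7 and 1.11 in GFP-D), Hrc, Gpnmb (541 against 20.0 and 54.6) and Grik3, and below both in 161. The furthest below were Serpinh1, Ctsz, Mmp14 and Ctsf (0.093 against 57.0 and 30.1), beside Nfe2l1, which was listed at 0 there.

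Between the 2 targeted arms, the libraries labelled FUBP1 held more of 6 genes than those labelled CIC, in a comparison that shares the CIC libraries with the one above. Serpinh1 (134 ± 32.9 against 0.190 ± 0.025 FPKM, SD over both states, n = 2 and 2, log2 difference 6.81, SE 0.29, adjusted p = 3.4e-04), Mmp14 (61.1 ± 39.2 against 0.049 ± 0.051), Mfsd10, Eml2 and Hdgfrp3 were among them, and 0 genes were lower. Fubp1 differed by -0.15 (SE 0.56, adjusted p = 0.934) and Cic by 1.07 (SE 0.35, adjusted p = 0.399). Cell cycle genes had positive estimates in 39 of 40 members (median 1.07, camera adjusted p = 9.5e-12) and cholesterol genes in 20 of 20 (1.20, camera adjusted p = 3.2e-07), whereas stress response genes had positive estimates in 4 of 20 (-1.39, camera adjusted p = 8.4e-07). With an estimated correlation none of the 3 held (adjusted p = 0.423, 0.509 and 0.386). Camera also called the p53 (-0.77, adjusted p = 2.8e-07), interferon (-0.93, 3.2e-07) and immediate early (-0.40, 0.0015) lists lower and the neuron list higher (0.54, 0.038), none of which held with an estimated correlation (adjusted p from 0.386 to 0.510). With quantile normalization 4 genes were higher and 1 lower, and the count was 19 with a pseudocount of 0.1 and 1 with group means. It was 10 without TRC or without 7, 2 without the proliferating library labelled CIC and 1 without any of the other 5 libraries.

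Whether the response to differentiation differed with either label was tested as a difference of differences. No gene was called for FUBP1 (0 of 11968 in limma, 99 at an unadjusted p under 0.05) or for CIC (0, with 512). The difference for Fubp1 itself in the FUBP1 arm was -0.66 (SE 1.11, adjusted p = 1.00), and that for Cic in the CIC arm was 0.82 (SE 0.46, adjusted p = 0.998). Kdm1a gave -0.20 (SE 0.45) and 0.37 (SE 0.45). Simulated genes changed by 4 log2 units were not recovered in this design, so differences of that size in single genes cannot be excluded.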

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

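No test in this part was chosen after its result was seen. 3 gene lists were picked out because limma's camera, at a preset correlation, found that the knockdown effect of a label differed between the states. The effect of the FUBP1 label on the FUBP family list was lower in the differentiating than in the proliferating state (median log2 difference -0.41, 2 of 11 members positive, adjusted p = 0.0108), with Ccnd2 at -1.59 and Peg3 at -1.45. That on the glycolysis and hypoxia list went the same way (median -0.51, 3 of 20 members positive, adjusted p = 0.00725), with Hk2 at -1.70. The effect of the CIC label on the stress response list was lower in the differentiating state (median -0.69, 5 of 20 members positive, adjusted p = 4.6e-04), with Atf3 at -5.42 (SE 0.60), Ddit3 at -4.15 and Ppp1r15a at -2.62, while Sdf2l1 stood at 2.50. Atf3 alone passed when adjusted over the list alone. With an estimated correlation none of the 3 calls held (adjusted p = 0.732, 0.732 and 0.830), each knockdown effect rests on 1 library per state, and Fubp1 is lowest in an NT library, GFP, though FUBP1-D lies below both NT libraries of its state.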

How the results depend on the processing

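The fits without library pairs, with TRC, 7 and the FUBP1 libraries alone, and with GFP and GFP-D as controls were chosen after the results were seen. Beyond the counts of called genes, values of named genes kept direction and side of the threshold in 874 cases, lost the call in 283 and changed sign in 13. Called lists kept direction and call in 655 cases and lost the call in 128, and camera's direction turned in 2. Both were the cell cycle list with the CIC label. Its median stayed negative without TRC (-0.015) and was positive with GFP and GFP-D as controls (0.11). All 38 list calls were lost with an estimated correlation and 35 with fry, which kept those of the cell cycle, astrocyte and CIC target lists for differentiation across arms. Where no cause is named, the cause was not tested.

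For differentiation across arms (4647 genes), 2906 were called with group means and 883 without 7 and FUBP1-D, against 4323 without GFP and GFP-D and 4653 with TRC, 7 and the FUBP1 libraries alone, and 2482 to 4863 with 1 library left out. For differentiation within NT (175), the count was 0 with a pseudocount of 5 (smallest adjusted p = 0.0624), without a filter (0.158) and without 7 and FUBP1-D (0.175), 323 with a filter at 5 FPKM, 277 with quantile normalization, and 0 to 480 with 1 library left out. For the CIC label (13), it was 35 and 4 with pseudocounts of 0.1 and 5, 2 without a filter, 8 with the filter at 5 FPKM, 1 with group means, 3 without GFP and GFP-D, 230 with these as the controls, and 2 to 18 with 1 library left out. For FUBP1 against CIC (6), it was 19 and 2 with pseudocounts of 0.1 and 5, 1 without a filter, 1 with group means, 0 without 7 and FUBP1-D (smallest adjusted p = 0.0701), and 1 to 10 with 1 library left out. The FUBP1 label gave 0 genes in limma in every alternative run, with 104 to 929 genes at an unadjusted p under 0.05.

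With the FUBP1 label, the log2 difference of Fubp1 (0.12) was -0.35 without GFP and GFP-D, and also with TRC, 7 and the FUBP1 libraries alone, and -0.32 to 0.46 with 1 library left out. That of Kdm1a was -0.0094 with quantile normalization, -0.014 with the median of ratios, -0.056 without GFP and GFP-D, and also with TRC, 7 and the FUBP1 libraries alone, and -0.16 to 0.16 with 1 library left out. The difference of the Fubp1 effect between states was -1.62 to 0.31 with 1 library left out. Kdm1a across arms was -0.060 with TRC, 7 and the FUBP1 libraries alone. The median of the cell cycle list with the CIC label was 0.11 with GFP and GFP-D as controls and -0.46 to -0.015 with 1 library left out.

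The replicate numbers pair no libraries across groups. A block on the name shared across states (GFP with GFP-D, FUBP1 with FUBP1-D, CIC with CIC-D) called 3534 genes for differentiation across arms, and the deviations of these pairs correlated across genes at 0.303, 0.277 and 0.267. Those of TRC and FUBP1-D, which share no name, correlated at 0.345. The differences between states could not be fitted without the knockdown library or without GFP and GFP-D, nor that for FUBP1 without 7 and FUBP1-D, nor differentiation within NT without GFP and GFP-D. The depth is unknown, and low values are coarser in the differentiating libraries.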

Other observations

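Apart from the splits of the libraries, the tests in this part were chosen after the results were seen, and the genes of this paragraph were chosen after their values were seen. Genes whose level can mark a culture differed between libraries with the same target. The Y-linked gene Eif2s3y stood at 4.55 FPKM in TRC, 9.33 in GFP, 22.6 in FUBP1 and 32.1 in CIC, and at 20.5 in 7, 9.50 in GFP-D, 8.02 in FUBP1-D and 59.1 in CIC-D. The tumour suppressor locus Cdkn2a was at 9.83, 0.863, 7.46 and 2.26 FPKM in the proliferating libraries TRC, GFP, FUBP1 and CIC and at 20.5, 0.741, 12.3 and 3.51 in the differentiating libraries 7, GFP-D, FUBP1-D and CIC-D. The clustered protocadherin Pcdhgb6 was at 18.3, 0.028, 5.51 and 0.014 and at 25.7, 0.021, 53.6 and 0.022 FPKM in the same orders.

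For the number of genes called across arms, 1 of 34 splits of the 8 libraries into 4 and 4 gave as many as the real split, which was that split itself. The real value was 4647 genes and the highest of the others 2. Every other split leaves the difference between states in its residual, so the size of this gap carries no weight. Only the rank, 1 of 34 splits, speaks against chance, and only where the libraries are exchanged freely. Only 8 of these splits part each of the 3 pairs that share a name across states (highest other 0), which is too few for a share under 0.05.

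Fubp1 was lowest in a library labelled non-targeted. An exchange of the proliferating libraries labelled GFP and FUBP1 is argued against by the deviations of GFP from its state's mean, whose correlation across genes with those of GFP-D exceeded that with FUBP1-D by 0.595 (0.303 against -0.292). A mixture of proliferating and differentiating cells in the GFP culture is argued against as the cause, since its Fubp1 level lay 9.16 FPKM below the lowest differentiating library (SD 2.23 over these 4), but other forms of partial differentiation were not tested and stay open: GFP correlated with the differentiating libraries at 0.843 to 0.881, against 0.757 to 0.832 for the other proliferating libraries, and held 13.3 FPKM of Aqp4 against 1.17 to 2.85. Labels crossed in 1 state between the control and the FUBP1 arm may contribute, since of 339 genes at least 1 log2 unit apart between FUBP1 and TRC 33.9% differed in the same direction between FUBP1-D and 7 (95% interval 28.9% to 39.2%, too narrow because genes are not independent), against 67.9% for GFP and TRC, TRC deviated with FUBP1-D (0.345) more than with 7 (0.032), and 4 Y-linked genes were 3.47 to 4.96 times as high in FUBP1 as in TRC but 2.37 to 3.94 times as high in 7 as in FUBP1-D, with 0.907 to 1.63 for 7 over FUBP1 and a less close 1.20 to 2.31 for FUBP1-D over TRC. The deviations of FUBP1 go against it, with 0.277 for FUBP1-D and -0.022 for 7, but over the protocadherins they gave 0.272 and 0.475. Over the protocadherins the deviations of TRC gave 0.814 for FUBP1-D and 0.573 for 7. Correlations over all genes, those of GFP included, may also follow how much a library divides, which was not tested. The cell cycle mean was highest in TRC and FUBP1 (5.72 each) among proliferating libraries. It was highest in FUBP1-D (2.55) among differentiating ones. Crossed labels and separate cultures thus cannot be told apart, and no label was changed here.

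Cell cycle genes were higher in FUBP1-D than in the other differentiating libraries. A small share of cells or reads like the proliferating libraries could give this: as the excess over the NT differentiating mean, in percent of the same excess in FUBP1 and TRC, 20 cell cycle genes had a median of 6.65%. Most of 40 other proliferation-specific genes also serve division, and the 7 that do not (chosen after their values were seen) had a median of 2.59% and ran from 0.463% (Nptx1) to 15.3% (Slco2a1), so carried-over cells or reads and ongoing division cannot be told apart. A lower FUBP1 level is a candidate explanation too, since Fubp1 in FUBP1-D lay 3.21 FPKM below the lower NT library, more than the SD of 2.23 FPKM over the 4 differentiating libraries. That SD includes FUBP1-D itself, and the gap does not show that a lower FUBP1 level raises cell cycle genes. The gap rests on 1 library, and the proliferating library with the lowest Fubp1, GFP, had a lower cell cycle mean than TRC (4.47 against 5.72).

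The 11 genes called lower with the CIC label, among them Serpinh1, Mmp14 and Ctsz, stood at 1.55 FPKM or less in both of its libraries. Failed estimates written as 0 in both libraries are argued against, since 11 of the 11 were above 0 in at least 1 of these libraries. Eml2 was listed at 0 in CIC and at 0.072 FPKM in CIC-D. Estimates that failed without being written as 0 were not tested. A separate culture for the CIC libraries may account for them: over 37 clustered protocadherins, the deviations of CIC and CIC-D correlated at 0.920 across genes, as those of GFP and GFP-D did at 0.862. Those of TRC and FUBP1-D, whose labels name different targets, correlated at 0.814, so such correlations do not always follow the labels. The values of clustered protocadherins are themselves uncertain. For a lower CIC level, 44.4% of the CIC targets had negative estimates, members went both ways, and the effect of the hairpin and of the culture cannot be told apart in libraries that share both.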
